A study of Homo sapiens with 18 samples.

How the data were processed

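The values were the deposited MAS5 signals, on a linear scale and already scaled by the authors so that the trimmed mean of each array (2 percent trimmed at each end) lay between 99.285 and 99.961. MAS5 is taken from the processing notes of the submitters, and its version is not given in the sources used here. Raw intensities and the detection calls that MAS5 makes were not used here. The table held 54675 probe sets on each of the 18 arrays, all of its columns were used, and 0 pairs of arrays held identical values.

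The signals were used on the scale log2(signal + 16) with the scaling of the authors kept. The 62 control probe sets were left out, and probe sets with a mean log2 value at or above the median of 5.1546, a signal of 19.62, were kept, which left 27307. Of all probe sets 41091 carried 1 gene symbol, 1801 several and 11721 none, and of those tested 22946, 1096 and 3265. Symbols came from the annotation of the array platform and were compared through Entrez IDs with a current human annotation (GRCh38.p14), in which 41037 were found and 0 symbols needed updating. For a gene with several probe sets the one with the highest mean was used, so a gene can be named through a probe set other than the one that was called. Probe sets that match several near-identical genes, such as those of AKR1C1 and AKR1C2 and of the MT1 genes, were kept under the symbol the platform gives.

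All 18 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean for each of the 6 groups and no block, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested with a threshold of 0.05. The contrasts were depleted against control cells at 24, 48 and 72 h and averaged over the 3 times. Further contrasts were the change of this effect from 24 h to 48 h and 72 h (singly and as an F-test), and 72 h against 24 h within control and within depleted cells. The prior degrees of freedom of the moderated variances were 4.57. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The groups, the transformation, the filter, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

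The sample numbering ran through all 6 groups once for each replicate number, so sets of 6 arrays pair the groups. After group means were taken away, arrays correlated at 0.302 to 0.602 within a set (45 pairs) and at -0.754 to 0.163 between sets, and each of the 18 arrays correlated best with an array of its own set. The first and second principal components of these deviations held 36.0 and 21.7 percent of their variance. Every comparison was therefore also fitted with the set as replicate block, and counts and list calls are compared with and without the block. The SE and adjusted p of single genes are from the fit without the block. All fits that left out 1 array were also made without it, so they ignore the pairing by set. The paired fit keeps every probe set that the unpaired fit called.

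Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, over 12319 genes with 1 probe set each. Of 29 lists fixed, 28 had at least 5 measured genes and were tested, and enteroendocrine markers, with 2 measured genes, were not. The lists were riboflavin transport and flavin cofactor synthesis, enzymes that use FAD or FMN, G1/S and DNA replication, G2/M and mitosis, p53 targets, unfolded protein response chaperones, ATF4 and amino acid response, complex I subunits, complex II to V subunits, mitochondrial fatty acid oxidation and NRF2 targets. They also covered iron and haem handling, cholesterol synthesis, fatty acid and triglyceride synthesis, hypoxia and glycolysis, folate and methionine cycle, ribosome biogenesis and MYC targets, and heat shock proteins. The remaining lists were NF-kB and inflammatory response, interferon response, SMAD and TGF-beta response, enterocyte differentiation, metallothioneins and zinc response, and markers of goblet cells, intestinal stem cells, fibroblasts, leukocytes and hepatocytes. Each test was repeated with a correlation estimated for each list and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. By fry 16 lists were called in the averaged effect. Beyond those called by camera these held enzymes that use FAD or FMN (adjusted p = 0.0365), p53 targets (0.00399), NF-kB (0.00751) and interferon response (0.0431). Mitochondrial fatty acid oxidation was called by camera but not by fry (0.0945).

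Genes were named by a rule. In each depletion contrast these were the 10 largest rises and the 10 largest falls past the test in which every depleted array lay beyond every control array of the same time, or the 5 with the smallest p in a direction where fewer than 5 qualified. To these came up to 4 members of each list with the smallest p in the averaged effect, all members of the riboflavin transport list, 5 rises and 5 falls in control cells between 24 and 72 h, and the 5 probe sets with the smallest p in the F-test. The alternatives without the arrays with suffixed titles, without set 2, and with the ACTB ratio as a covariate were chosen after seeing the data. RNA quality was read from the log2 ratio of 3' to 5' signal of the ACTB and GAPDH control probe sets, and the GAPDH ratio lay between -0.311 and 0.0922.

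The code was tested on simulated data with 200 changed probe sets of 27307. In the averaged effect it recovered 18, 68, 90 and 98 percent of changes of 1.5, 2, 3 and 4-fold with 1 false call, and with the replicate block 36, 82, 94 and 100 percent with 9 false calls. At 24 h it recovered 0, 8, 54 and 80 percent with 0 false calls, and 10, 38, 78 and 94 percent with 3 false calls with the block. At 48 h these were 0, 6, 58 and 76 percent with 0 false calls (4, 44, 74 and 92 percent with 7 with the block), and at 72 h 0, 8, 54 and 70 percent with 1 (6, 36, 80 and 88 percent with 8). Of simulated lists 5 of 5 shifted by 0.3 on the log2 scale were called, and 0 of 25 unshifted ones. The simulated noise was drawn independently for each probe set and the lists at random. The simulation therefore cannot show how often lists of correlated genes are called falsely.

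The depleted cells were grown in medium without riboflavin. The labels do not say which arms received dialysed serum, what the suffix of 3 titles stands for, or what the sets of the sample numbering were.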

Results

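Gene expression was measured in Caco-2 cells, a human colon carcinoma line used as a model of the intestinal epithelium, grown in standard medium or in medium without riboflavin (vitamin B2, the precursor of the flavin cofactors FMN and FAD). The series is about impaired proliferation of intestinal cells under riboflavin depletion. Cells of each medium were collected at 24, 48 and 72 h, giving 6 groups of 3 arrays and 18 Affymetrix arrays in all. The arrays carried a numbering that ran through all 6 groups 3 times, so each replicate number formed a set of 6 arrays with 1 array of every group. The median signal of an array was 18.4 to 22.0 in set 1, 25.6 to 31.3 in set 2 and 19.1 to 23.3 in set 3. The highest signal lay between 27380 and 31410 in set 2 against 6904.8 to 8574.5 in the other sets. The number of arrays limits the precision of every value. Nothing in the labels says whether replicates were separate cultures, so the p-values measure only the spread between these samples.

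Averaged over the 3 times, AKR1C3, an aldo-keto reductase that reduces carbonyl compounds and steroids, was 3.06-fold higher in depleted cells (log2 1.62, SE 0.19, adjusted p = 0.000128, 9 arrays against 9, limma). The probe sets assigned to the related AKR1C2 and AKR1C1 rose by 3.07 (SE 0.16) and 2.92 (SE 0.17) on the log2 scale, with adjusted p = 3.99e-08 and 7.74e-08. These genes are nearly identical in sequence, so which of them carried the signal is uncertain. Also higher were EMP1, an epithelial membrane protein (log2 1.97, SE 0.20, adjusted p = 4.61e-05), and CLIC5, a chloride intracellular channel family member (log2 1.61, SE 0.14, adjusted p = 9.5e-06). The calcium-binding protein S100P rose by 1.31 (SE 0.14) and the secreted protease inhibitor SLPI by 1.30 (SE 0.15). ALDH1A1, a retinaldehyde dehydrogenase, rose by 1.34 (SE 0.25), and the long noncoding RNAs EPB41L4A-AS1 and MALAT1 rose by 1.30 (SE 0.15) and 1.17 (SE 0.18).

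Among the genes lower in depleted cells, AFP, the fetal serum protein alpha-fetoprotein, changed by -2.23 (SE 0.20, adjusted p = 9.5e-06, limma) and ALB, serum albumin, by -2.18 (SE 0.26, adjusted p = 0.000176). The fibrinogen chains FGB and FGG changed by -1.39 (SE 0.22) and -1.35 (SE 0.18). Lower too were CHI3L1, a secreted chitinase-like protein (log2 -1.89, SE 0.17, adjusted p = 9.69e-06), and CYP4X1, an orphan cytochrome P450 (log2 -1.71, SE 0.14, adjusted p = 5.87e-06). The peptide hormone UTS2 was at -1.51 (SE 0.27), the basement membrane protein NID2 at -1.06 (SE 0.19), and FDPS, farnesyl diphosphate synthase of the mevalonate pathway, at -1.05 (SE 0.19). Each gene named so far lay on the same side in all 9 comparisons of a depleted with a control array of the same set and time. The rule for naming genes asked for this separation of the arrays, so it is no separate evidence. BCCIP, a cell-cycle regulator that binds BRCA2, was called lower through 2 probe sets, while its most abundant probe set was at -0.12 (SE 0.14) and did not pass (adjusted p = 0.743).

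In the averaged effect limma called 1162 of 27307 probe sets at an adjusted p of 0.05, 745 higher and 417 lower in depleted cells. This split depended on the scaling, with 427 higher and 380 lower when arrays were centred on the 75th percentile and 615 and 440 after quantile normalization. With the replicate block, which compares arrays within each set, 4097 were called, 2334 higher and 1763 lower, and all 1162 stayed called in the same direction. No single array left out moved the count without the block by more than 1.5 times. Fold changes were taken after adding 16 to each signal, which understates them for weakly expressed genes.

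Genes of the cell cycle were lower in depleted cells. Of 42 measured genes of the G1/S and DNA replication list, 12 fell and none rose, 20 when adjusted over the list alone and 24 with the replicate block. Among them were UHRF1, which keeps DNA methylation through replication (log2 -0.77, SE 0.17, adjusted p = 0.0154), the replication initiation helicase subunit MCM4 (-0.58, SE 0.11), the sliding clamp PCNA (-0.51, SE 0.11) and the thymidylate synthase TYMS (-0.44, SE 0.10). The list as a whole was called lower by camera (median log2 -0.34, adjusted p = 1.68e-13), also with an estimated correlation (adjusted p = 0.00391). Of 44 genes of G2/M and mitosis, 3 fell, 3 adjusted over the list alone and 15 with the block, namely cyclin CCNB1 (-0.59, SE 0.14), the spindle checkpoint kinase BUB1 (-0.53, SE 0.11) and the spindle protein ASPM (-0.47, SE 0.10). That list was called lower (median -0.25, adjusted p = 1.23e-07), but not with an estimated correlation (adjusted p = 0.181 with an estimated correlation), while the block with an estimated correlation did call it (adjusted p = 0.0456). The call of CCNB1 was lost in 2 of the 18 fits that left out 1 array.

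Of 27 target genes of NRF2, a transcription factor of the antioxidant response, 12 rose and none fell, 15 adjusted over the list alone, and 16 rose and 1 fell with the block (median 0.47, adjusted p = 2.59e-10, and 0.000163 with an estimated correlation). They included thioredoxin reductase TXNRD1 (log2 0.98, SE 0.15, adjusted p = 0.00165), the subunits GCLC (0.88, SE 0.15) and GCLM (0.71, SE 0.13) of the rate-limiting enzyme of glutathione synthesis, the sulfiredoxin SRXN1 (0.89, SE 0.15) and the cystine transporter SLC7A11 (1.19, SE 0.13). The rise of GCLM came mostly from 72 h. Its log2 level was 7.52 to 8.01 in control and 7.60 to 8.02 in depleted cells at 24 h. At 72 h these were 7.25 to 7.36 and 8.88 to 9.23. Of 9 metallothioneins and zinc response genes, 4 rose, 4 adjusted over the list alone and 5 with the block (median 0.45, adjusted p = 0.000457, and 0.0311 with an estimated correlation), among them MT2A (1.02, SE 0.23) and MT1X (1.44, SE 0.23). Probe sets of the MT1 genes match several near-identical members, so their assignment is uncertain. By camera the metallothionein list was called at 72 h (adjusted p = 1.15e-06) but not at 24 h (0.524) or 48 h (0.48). Of 33 ATF4 and amino acid response genes, 9 rose, 13 adjusted over the list alone and 17 with the block (median 0.30, adjusted p = 5.96e-10, and 0.0178 with an estimated correlation). Among these, besides SLC7A11, were DDIT4, an inhibitor of mTORC1 signalling (1.38, SE 0.17), the cystathionine gamma-lyase CTH (1.11, SE 0.12), the transcription factor ATF3 (0.99, SE 0.18) and asparagine synthetase ASNS (0.61, SE 0.16). At 72 h alone the ATF4 list was not called by camera (median 0.13, adjusted p = 0.116), with 5 genes higher and 2 lower.

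Genes of lipid synthesis and respiration were lower. Of 21 cholesterol synthesis genes, 5 fell, 12 adjusted over the list alone and 15 with the block, including FDPS and the acetoacetyl-CoA thiolase ACAT2 (-1.01, SE 0.13). The list was called (median -0.43, adjusted p = 4.91e-10, and 0.000163 with an estimated correlation). Fatty acid and triglyceride synthesis was called lower (median -0.23, adjusted p = 0.00162) with 4 of 20 genes lower and none higher, 5 lower and 1 higher adjusted over the list alone, and 6 lower and 2 higher with the block. The call was lost with an estimated correlation (adjusted p = 0.206 with an estimated correlation), but held with the block and an estimated correlation (adjusted p = 0.0456). SCD, the stearoyl-CoA desaturase (-0.70, SE 0.10), ELOVL6, a fatty acid elongase (-0.96, SE 0.21), and ACLY, ATP citrate lyase (-0.59, SE 0.11), were among the lower genes. Of 35 subunits of respiratory complexes II to V, 4 fell, 5 adjusted over the list alone and 19 with the block, such as the ATP synthase subunits ATP5MC1 (-0.97, SE 0.14) and ATP5PD (-0.47, SE 0.11). That list was called (median -0.26, adjusted p = 3.34e-10, and 0.0206 with an estimated correlation). Of 33 complex I subunits, 3 fell, 6 adjusted over the list alone and 18 with the block, with NDUFC1 at -0.53 (SE 0.10) and NDUFB2 at -0.45 (SE 0.10). Complex I was called lower (median -0.30, adjusted p = 1.78e-09), but not with an estimated correlation (adjusted p = 0.0896 with an estimated correlation). It was called with the block and an estimated correlation (adjusted p = 0.0354).

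Markers of hepatocytes were lower: 7 of 12 measured markers fell and none rose, and adjusted over the list alone 7 fell and 1 rose, as with the block. Of the 18 markers in that list these 12 were expressed above the filter in Caco-2 cells. Besides AFP, ALB, FGB and FGG these were the fibrinogen chain FGA (-0.89, SE 0.20), the protease inhibitor SERPINA1 (-0.75, SE 0.12) and the urea cycle enzyme CPS1 (-0.74, SE 0.13). The list was called (median -0.75, adjusted p = 8.71e-08, and 0.0311 with an estimated correlation). Chaperones of the unfolded protein response were called lower (median -0.24, adjusted p = 0.00159, and 0.0178 with an estimated correlation). Of these 24 genes SDF2L1 (-0.91, SE 0.17) and CRELD2 (-0.58, SE 0.16) were lower, 3 adjusted over the list alone, and 9 lower and 1 higher with the block. Heat shock proteins were called lower (median -0.26, adjusted p = 0.0283, and adjusted p = 0.108 with an estimated correlation, which ended the call). Of these 15 genes the co-chaperone DNAJB4 rose (0.75, SE 0.17) and HSPA4L and HSPE1 fell (-0.62, SE 0.13, and -0.38, SE 0.10), and 3 fell and 1 rose adjusted over the list alone. That call was also lost without control 24 h replicate 2 (adjusted p = 0.0596) and without control 72 h replicate 2 (adjusted p = 0.0540). Mitochondrial fatty acid oxidation was called lower (median -0.23, adjusted p = 0.0208, and adjusted p = 0.312 with an estimated correlation). In it CPT1A, which carries fatty acids into mitochondria, rose (0.79, SE 0.17) and ECHS1, an enoyl-CoA hydratase, fell (-0.48, SE 0.10) among 23 genes. In that list 2 fell and 1 rose adjusted over the list alone, and 8 fell and 2 rose with the block. The call was lost without replicate 1 of control cells at 24, 48 and 72 h (adjusted p = 0.0672, 0.0645 and 0.0730) and without depleted replicate 2 at 48 and 72 h (adjusted p = 0.0925 and 0.0692). The calls of CRELD2 and HSPE1 were lost in 14 and 12 of the 18 fits that left out 1 array.

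**Figure D1:**
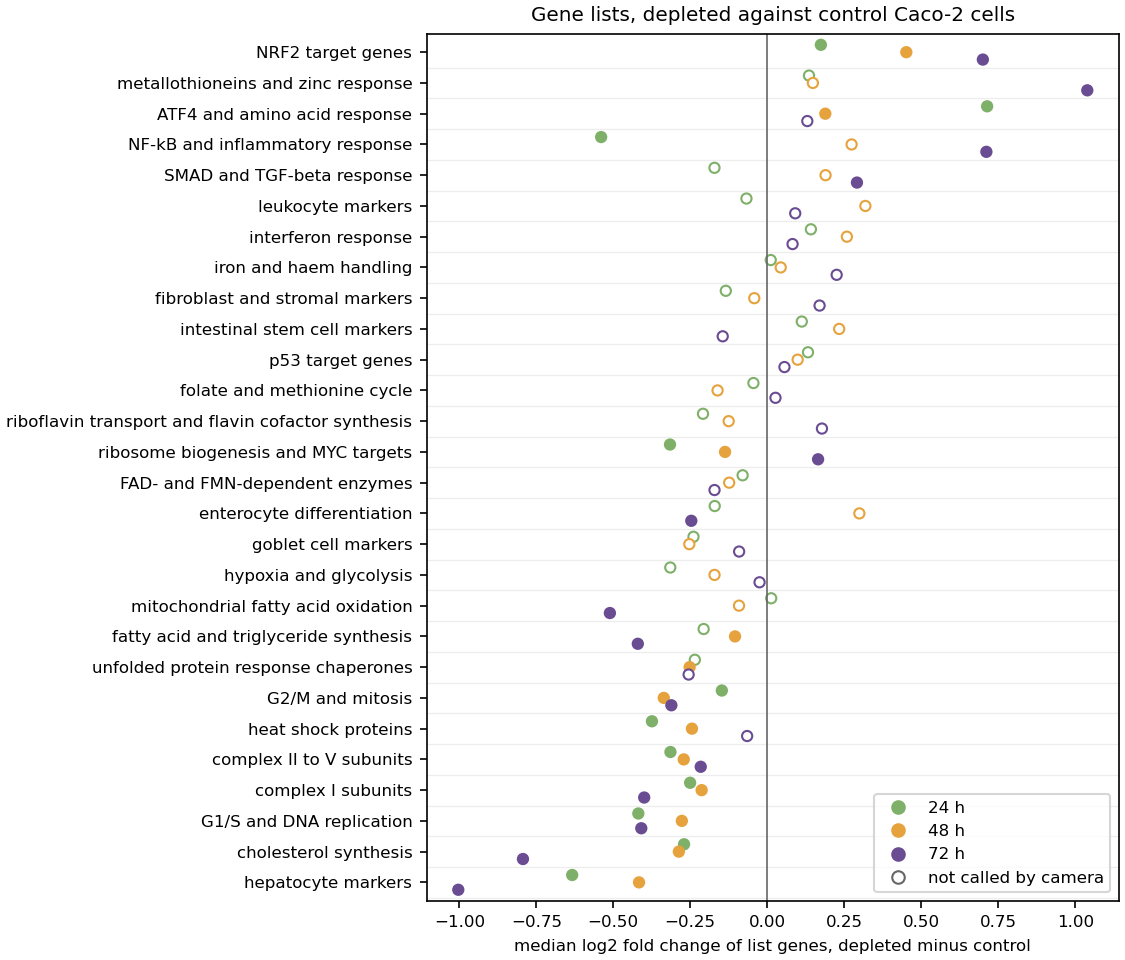
Median log2 fold change (depleted minus control cells, x axis) of the measured genes of each of the 28 lists (y axis) at 24, 48 and 72 h, with filled points for lists called by camera at an adjusted p of 0.05 and open points for the others. NRF2 targets lay at 0.17, 0.45 and 0.70 at the 3 times, and the NF-kB list lay at -0.54 at 24 h and 0.71 at 72 h.

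Genes that take up riboflavin or turn it into cofactors did not pass the test. The transporters SLC52A2 and SLC52A3 were at -0.03 (SE 0.18) and 0.14 (SE 0.21). Riboflavin kinase RFK was at -0.08 (SE 0.23), FAD synthase FLAD1 at -0.08 (SE 0.13) and the mitochondrial folate and FAD carrier SLC25A32 at -0.05 (SE 0.11). None passed at any time, and the list gave adjusted p = 0.832. Of 61 measured enzymes that use FAD or FMN, TXNRD1 rose and the peroxisomal oxidase ACOX2 (-0.74, SE 0.12), PCYOX1 (-0.54, SE 0.14) and AIFM1 (-0.45, SE 0.12) fell. In this list 2 rose and 6 fell adjusted over the list alone, and 4 rose and 14 fell with the block (list adjusted p = 0.06 by camera, and 0.0365 by fry). The calls of PCYOX1 and AIFM1 were lost in 12 and 16 of the 18 fits that left out 1 array. In the averaged effect 13 of 28 lists were called, 3 higher and 10 lower, the block called 13, and 8 kept their call with an estimated correlation, 11 with the block as well.

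The remaining lists were not called by camera in the averaged effect, though fry called the NF-kB, p53 and interferon lists. Ribosome biogenesis and MYC targets gave adjusted p = 0.0957, with 1 of 30 genes lower and 1 adjusted over the list alone. Enterocyte differentiation gave 0.117, the NF-kB and inflammatory response 0.134 with 0 of 16 genes past the test (0 adjusted over the list alone), and p53 targets 0.147. The interferon response gave 0.147, with 1 of 15 genes higher, IRF7 (0.72, SE 0.17), and 2 adjusted over the list alone. SMAD and TGF-beta response gave 0.147, with 1 of 19 higher, PMEPA1 (0.76, SE 0.14), and 4 higher and 2 lower adjusted over the list alone. Hypoxia and glycolysis gave 0.371 and the folate and methionine cycle 0.469 (CTH higher and TYMS lower of 20, and 1 higher and 2 lower adjusted over the list alone). Iron and haem handling gave 0.862 (1 higher and 1 lower of 21, and 2 and 2 adjusted over the list alone). Of the cell type markers, goblet cells gave 0.268 (0 of 5 past the test, 1 lower adjusted over the list alone) and leukocytes 0.268 (0 of 9, 0 adjusted over the list alone). Intestinal stem cells gave 0.705, with TNFRSF19 lower (-0.73, SE 0.14) of 10 and 1 higher and 1 lower adjusted over the list alone. Fibroblasts gave 0.957, with SPARC higher (0.78, SE 0.21) and PDGFRA lower (-1.07, SE 0.18) of 11, and 1 higher and 2 lower adjusted over the list alone. SPARC lost its call in 15 of the 18 fits that left out 1 array. List median, mean and test differed in sign for p53 targets (median -0.00, mean 0.16, test higher), stem cell markers (median 0.04, mean -0.05, test lower) and fibroblast markers (median 0.06, mean -0.01, test higher).

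At 24 h the probe sets of AKR1C2 (2.76, SE 0.28) and AKR1C1 (2.69, SE 0.30) had the largest rises. DDIT4 rose by 2.50 (SE 0.30, adjusted p = 0.00139, limma, n = 3 arrays per group), the cystine transporter SLC7A11 by 1.81 (SE 0.23), CTH by 1.75 (SE 0.22) and the secreted glycoprotein STC2 by 1.64 (SE 0.23). KLHL24, a substrate adaptor for ubiquitin ligases, rose by 1.88 (SE 0.25), EPB41L4A-AS1 by 1.83 (SE 0.25), CLIC5 by 1.70 (SE 0.25) and S100P by 1.68 (SE 0.25). The collagenase MMP1 was lower at -2.37 (SE 0.29, adjusted p = 0.00161), as were AFP (-1.84, SE 0.35), the intestinal lectin REG4 (-1.57, SE 0.29) and CYP4X1 (-1.57, SE 0.25). So were the trefoil peptide TFF1 (-1.37, SE 0.24), the basement membrane protein NID1 (-1.12, SE 0.22), the serine protease HABP2 (-1.10, SE 0.19) and the chromatin protein HMGA2 (-0.92, SE 0.17). FGB and the matrix glycoprotein THBS1 were each called lower by 1 probe set, while their most abundant probe sets were at -1.17 and -0.53 and did not pass (adjusted p = 0.338 and 0.54). Limma called 59 probe sets at 24 h, 48 higher and 11 lower, and 646 with the replicate block, 424 higher and 222 lower.

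Of the ATF4 and amino acid response list, 6 of 33 genes rose at 24 h, 19 adjusted over the list alone and 16 with the block. The list was called higher (median 0.71, adjusted p = 6.12e-23, and 0.00235 with an estimated correlation). NRF2 targets were called higher (median 0.17, mean 0.46, adjusted p = 2.62e-05) with 3 of 27 higher and 4 adjusted over the list alone. These 3 were AKR1C1 and AKR1C2, whose probe sets cannot be told apart with certainty, and SLC7A11, which is also in the ATF4 list. Called lower were G1/S and DNA replication (adjusted p = 5.26e-10), complexes II to V (1.9e-08), ribosome biogenesis and MYC targets (5.79e-07, median -0.32), NF-kB and inflammatory response (6.61e-06, median -0.54), cholesterol synthesis (3.21e-05) and heat shock proteins (0.000519). None of the genes of these lower lists passed on its own, while adjusted over the list alone 3, 0, 1, 4, 1 and 1 fell. A further 3 lower calls were lost with an estimated correlation, hepatocyte markers (1 of 12 lower, 6 lower and 1 higher adjusted over the list alone, 8.43e-06, and adjusted p = 0.0596 with an estimated correlation), complex I (1.44e-05, and 0.213) and G2/M (0.00994, and 0.46). Of these, hepatocyte markers were called with the block and an estimated correlation (adjusted p = 0.0401). The G2/M call was also lost at 24 h without control replicate 1 (adjusted p = 0.153) or 3 (0.0550) and without depleted replicate 2 (0.0556) or 3 (0.142). The chaperones of the unfolded protein response were called lower only with the block (adjusted p = 0.0351, against 0.0651 without it), and not with the block and an estimated correlation (adjusted p = 0.0628).

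Without the block the counts at 24 h rested on few arrays. Without depleted 24 h replicate 1 the count was 28, without control 24 h replicate 2 it was 20, and without depleted 24 h replicate 2 it was 25. Without replicate 3 of control and depleted cells at 24 h it was 27 and 35, against 59 with all arrays. Without the 3 arrays whose titles carried a suffix, all in set 2, 3 probe sets were called. With the block 309 were called without these arrays, and 57 of the 59 calls stayed called in the same direction. Without all of set 2, and without the block, 1 probe set was called. Leaving out the suffixed arrays and leaving out set 2 were both chosen after seeing the data. In set 2 the ratio of 3' to 5' signal of the ACTB control probe sets, a measure of RNA quality, was 0.51 higher on the log2 scale in the depleted than in the control array at 24 h, against 0.13 and 0.10 in sets 1 and 3. Calls of AFP, REG4, NID1, HMGA2, HABP2, CYP4X1 and TFF1 at 24 h were lost in 10, 8, 16, 11, 5, 4 and 4 of the 18 fits that left out 1 array.

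At 48 h the genes called higher were again led by AKR1C2 (log2 2.93, SE 0.28, adjusted p = 0.000367, limma, n = 3 per group) and AKR1C1 (2.86, SE 0.30). They were followed by AKR1C3 (1.84, SE 0.33), S100P (1.5, SE 0.25), SLPI (1.5, SE 0.26), SETBP1, which binds the SET oncoprotein (1.47, SE 0.27), the interleukin-6 receptor IL6R (1.23, SE 0.20) and the glutathione peroxidase GPX2 (1.21, SE 0.22). AFP (-2.13, SE 0.35), CHI3L1 (-1.67, SE 0.30) and CYP4X1 (-1.45, SE 0.25) were lower. CLIC5 and RRAGD, a GTPase that relays amino acid supply to mTORC1, were called higher by another probe set than the most abundant, which was at 0.88 (adjusted p = 0.377) and 1.34 (adjusted p = 0.0509). ALB (-2.18, adjusted p = 0.124) did not pass, nor did the disintegrin ADAM22, which was taken up through a lower probe set while its most abundant one was at 0.54 (adjusted p = 0.885). Limma called 22 probe sets, 19 higher and 3 lower, and 189 with the replicate block, 144 higher and 45 lower.

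In the lists at 48 h, NRF2 targets were called higher (median 0.45, adjusted p = 3.56e-07, 3 of 27 genes higher, 4 adjusted over the list alone). These 3 were the related AKR1C1, AKR1C2 and AKR1C3, and which of them carried the signal is uncertain. Lower were G1/S and DNA replication (1.23e-07), cholesterol synthesis (8.01e-05) and the chaperones of the unfolded protein response (0.000392), all 4 lists also with an estimated correlation. No gene of those lower lists passed, and adjusted over the list alone 0, 1 and 0 did. A further 8 calls were lost with an estimated correlation. These were lower G2/M (adjusted p = 6.54e-10, and 0.134 with an estimated correlation), complexes II to V (1.23e-07, and 0.0598), complex I (4.11e-05, and 0.25) and hepatocyte markers (4.11e-05, and 0.126). To these came lower ribosome biogenesis (0.0248, and 0.25), heat shock proteins (0.0451, and 0.162), fatty acid and triglyceride synthesis (0.0482, and 0.402) and higher ATF4 targets (0.0232, and 0.27). Of these 8, G2/M was called with the block and an estimated correlation (adjusted p = 0.0352). Fatty acid and triglyceride synthesis was not called with the block (adjusted p = 0.0793).

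Several list calls at 48 h also ended without single arrays. Fatty acid and triglyceride synthesis lost its call without replicate 1 of control cells at 24 h (adjusted p = 0.0543) and 72 h (0.0506) and of depleted cells at 48 h (0.466) and 72 h (0.0524). It also lost it without replicate 2 of depleted cells at 24 h (0.0513) and 72 h (0.0504) and of control cells at 48 h (0.384), and without replicate 3 of control cells at 24 h (0.0561) and 48 h (0.138). At 48 h ribosome biogenesis lost it without control replicate 1 (0.0890), depleted replicate 2 (0.174) and control replicate 3 (0.0851). Heat shock proteins lost it without depleted replicate 1 (0.0798), control replicate 2 (0.157) and replicate 3 of control and depleted cells (0.116 and 0.111), and ATF4 targets without depleted replicate 1 (0.0798), control replicate 2 (0.652) and depleted replicate 3 (0.0658).

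The count of 22 fell to 6 without replicate 1 of control or of depleted cells at 48 h, to 12 and 7 without replicate 2 of control and depleted cells at 48 h, and to 5 and 3 without replicate 3 of these groups. It was 13 without depleted 24 h replicate 2, 12 and 11 without replicate 1 of control and depleted cells at 72 h, and 14 without replicate 3 of either at 72 h. Without the suffixed arrays it was 7. With the block it was 109 without them, and 19 of the 22 calls stayed called in the same direction. In set 2 the ACTB ratio of the depleted array at 48 h was -0.59 from that of the control array, against 0.02 and 0.10 in sets 1 and 3. The 48 h calls of AKR1C3, S100P, SLPI, SETBP1, IL6R, GPX2, AFP, CHI3L1 and CYP4X1 were lost in 16, 6, 15, 15, 7, 18, 5, 15 and 12 of the 18 fits that left out 1 array.

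At 72 h EMP1 was 11.8-fold higher (log2 3.56, SE 0.35, adjusted p = 4.05e-05, limma, n = 3 per group), and NPPB, which encodes a natriuretic peptide, 10.5-fold (log2 3.39, SE 0.36, adjusted p = 7.33e-05). AKR1C2 and AKR1C1 rose by 3.53 (SE 0.28) and 3.22 (SE 0.30), the inducible cyclooxygenase PTGS2 by 2.84 (SE 0.33), RGCC, a regulator of the cell cycle, by 2.76 (SE 0.28) and the retinoic acid-induced receptor GPRC5A by 2.53 (SE 0.27). The metallothionein probe sets of MT1H (2.98, SE 0.39), MT1X (2.74, SE 0.40) and MT1HL1 (3.21, SE 0.80) rose, MT1HL1 losing its call without any 1 of the 6 arrays at 72 h. Lower were AFP (-2.72, SE 0.35), CHI3L1 (-2.66, SE 0.30), the laminin chain LAMA1 (-2.57, SE 0.36), the fatty acid binding protein FABP1 (-2.50, SE 0.58) and ALB (-2.36, SE 0.45). So were the ciliary protein RPGRIP1L (-2.14, SE 0.26), GAS2, a cytoskeletal protein of growth arrest (-2.14, SE 0.35), CYP4X1 (-2.10, SE 0.25), FGG (-2.06, SE 0.32) and the peptide hormone APELA (-2.06, SE 0.45). FABP1 lost its call without control 72 h replicate 1 (adjusted p = 0.105) or 3 (0.0590) and depleted 72 h replicate 2 (0.107), and APELA without control 72 h replicate 1 (0.0711) or depleted 72 h replicate 3 (0.0837). Limma called 1136 probe sets, 609 higher and 527 lower, and 3631 with the replicate block, 1748 higher and 1883 lower.

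At 72 h 5 lists were called with a preset and with an estimated correlation. NRF2 targets rose (10 of 27 genes higher, 13 higher and 1 lower adjusted over the list alone, median 0.70, adjusted p = 1.77e-09), with TXNRD1 at 1.78 (SE 0.26). The NF-kB and inflammatory list rose (3 of 16 higher, 9 adjusted over the list alone, median 0.71, adjusted p = 6.76e-08) with the chemokines CCL20 (2.38, SE 0.47) and CXCL1 (1.09, SE 0.25) and the NF-kB inhibitor TNFAIP3 (0.71, SE 0.19). Metallothioneins rose (4 of 9, 6 adjusted over the list alone, median 1.04, adjusted p = 1.15e-06). Cholesterol synthesis fell (6 of 21, 11 adjusted over the list alone, median -0.79, adjusted p = 8.47e-08). G1/S and DNA replication fell (6 of 42, 8 adjusted over the list alone, median -0.41, adjusted p = 5.18e-07), with UHRF1 at -1.39 (SE 0.29).

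Another 9 calls at 72 h were lost with an estimated correlation. Hepatocyte markers were lower (7 of 12, 7 adjusted over the list alone, adjusted p = 1.83e-06, and adjusted p = 0.0653 with an estimated correlation). Fatty acid oxidation (2 of 23, median -0.51, 0.000132), fatty acid and triglyceride synthesis (0.001), complex I (1.11e-05), complexes II to V (0.00155) and enterocyte differentiation (0.0179) were lower, each with adjusted p = 0.188 with an estimated correlation. Adjusted over the list alone 5, 5, 3, 3 and 6 genes of these lists fell, and 1 and 2 of fatty acid synthesis and enterocyte differentiation rose. G2/M was lower (0.00638, and 0.381 with an estimated correlation), and ribosome biogenesis and MYC targets (0.0146) and the SMAD and TGF-beta response (0.0148) were higher, both with adjusted p = 0.188 with an estimated correlation. Hepatocyte markers and fatty acid and triglyceride synthesis were called with the block and an estimated correlation (adjusted p = 0.0327 and 0.0408). Without single arrays at 72 h the calls of 4 of these lists were lost. They were G2/M (control replicate 1, 0.121, and depleted replicate 2, 0.128), enterocyte differentiation (the same arrays, 0.0590 and 0.0697), SMAD (control replicate 1, 0.121) and ribosome biogenesis (depleted replicate 1, 0.0684, control replicate 2, 0.0805, and depleted replicate 3, 0.0578). The count of 1136 was 584, 688 and 638 without control 72 h replicate 1, 2 and 3, and 646, 646 and 576 without depleted 72 h replicate 1, 2 and 3. Without all of set 2 it was 717, a setting chosen after seeing the data.

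**Figure D2:**
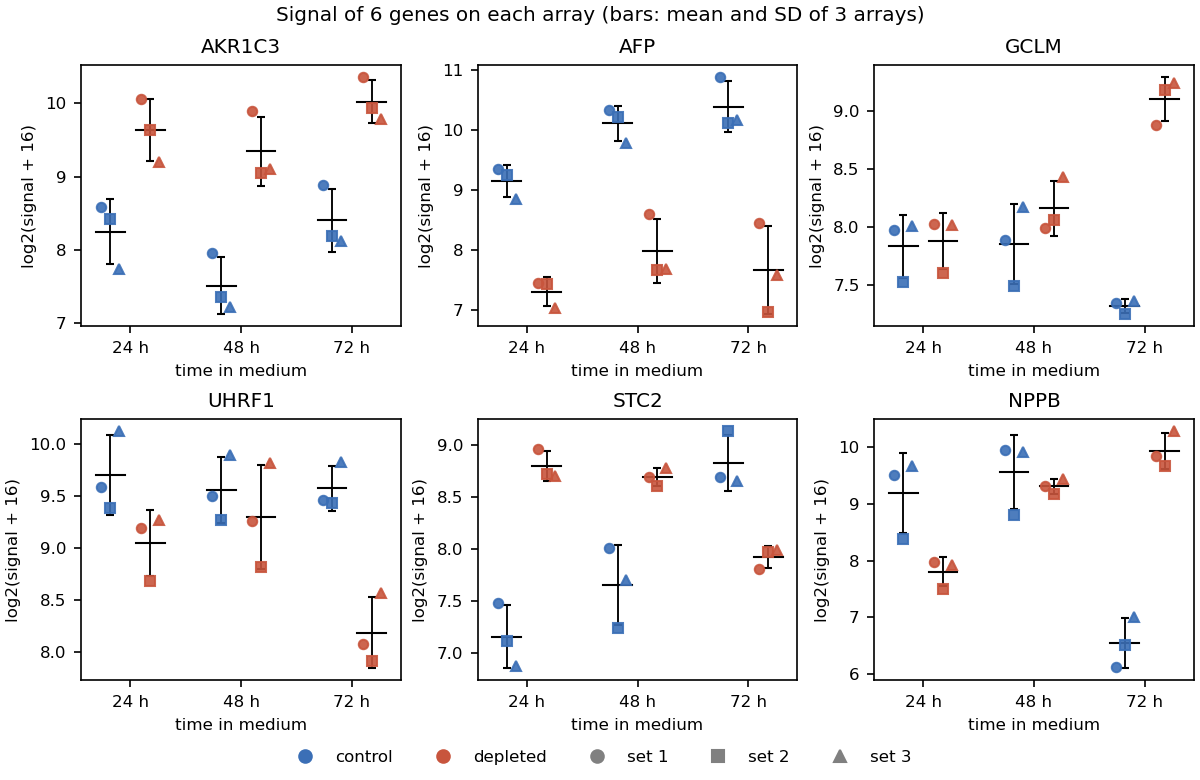
Level of 6 genes on each of the 18 arrays (y axis, log2 of the signal plus 16) against time (x axis, 24, 48 and 72 h) for control and depleted cells, with points for arrays and a mean with SD for each group of 3. AFP lay between 8.85 and 10.9 in control cells and between 6.98 and 8.61 in depleted cells, while NPPB fell from 8.39 to 9.67 at 24 h to 6.13 to 7.01 at 72 h in control cells and lay between 9.66 and 10.3 in depleted cells at 72 h.

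The depletion effect was compared between 72 h and 24 h directly. NPPB changed most, its effect being 4.78 higher at 72 h (SE 0.50, adjusted p = 0.000595, limma), from -1.39 at 24 h (adjusted p = 0.164) to 3.39 at 72 h. The effects on CCL20 (4.48, SE 0.66), PTGS2 (2.94, SE 0.47), RGCC (2.64, SE 0.40) and MMP1 (2.58, SE 0.41) were also higher at 72 h. The effect on ALDH1L2, a mitochondrial folate enzyme induced by ATF4, changed by -2.54 (SE 0.28) to 72 h, turning from 1.42 to -1.12, and that on STC2 by -2.54 (SE 0.32), from 1.64 to -0.90. Limma called 176 probe sets, 96 with a higher and 80 with a lower effect at 72 h, and 1251 with the replicate block (511 and 740). Centred on the 75th percentile these were 70 and 24, and after quantile normalization 97 and 60. The F-test over all 3 times called 85 (953 with the block), and 48 h against 24 h called 0 with limma (854 at an unadjusted p of 0.05, and 0 with the block, 2214 unadjusted). By the F-test the effect on NPPB (adjusted p = 0.00155), ALDH1L2 (0.00281), THBS1 (0.028) and GPRC5A (0.0397) differed between times, and MT1X was called through another than its most abundant probe set (0.188). The 72 h against 24 h calls of THBS1 and GPRC5A were each lost in 7 of the 18 fits that left out 1 array. Those of CCL20, PTGS2, RGCC, MMP1 and STC2 were not followed through these fits.

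Between 72 h and 24 h the effect on 9 lists differed. The NF-kB list had the largest shift (median 1.25, adjusted p = 8.06e-14, 3 of 16 genes higher and 10 adjusted over the list alone). Metallothioneins (median 1.09, 4.13e-05, 2 of 9 higher and 5 adjusted over the list alone), ribosome biogenesis (median 0.56, 2.76e-08) and NRF2 targets (median 0.29, 0.00472) shifted up. ATF4 targets shifted down (median -0.62, adjusted p = 2.49e-07, 4 of 33 lower, and 9 lower and 2 higher adjusted over the list alone). Fatty acid oxidation (0.00161) and cholesterol synthesis (0.0491) shifted down and heat shock proteins (0.0154) and SMAD (0.0217) up, with adjusted p = 0.233, 0.0856, 0.0856 and 0.141 with an estimated correlation, which ended these calls. The block called 13 lists, adding leukocyte markers, riboflavin transport, hypoxia and hepatocyte markers, each with adjusted p = 0.0365. These calls were lost with the block and an estimated correlation (adjusted p = 0.227, 0.128, 0.174 and 0.233 in that order). So were those of ATF4 targets (adjusted p = 0.128), NRF2 targets (0.128) and metallothioneins (0.0677), which held with an estimated correlation without the block.

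Probe sets called at more than 1 time overlapped. Of the probe sets called higher at 24 h, 19 were also called higher at 72 h, against 1.07 for independent calls, and 6 were called lower at both times against 0.212. At 24 and 72 h 4 were called in opposite directions. At 24 and 48 h 11 were called higher at both times (0.0334 for independent calls), and at 48 and 72 h 14 (0.424). With the block 65 were higher and 23 lower at both 24 and 48 h, and 74 higher and 30 lower at both 48 and 72 h, with 6 opposite. With it 130 were higher and 87 lower at both 24 and 72 h, and 42 opposite. Across probe sets, which are not independent, the correlation of log2 fold changes was 0.312 between 24 and 48 h, 0.165 between 24 and 72 h and 0.266 between 48 and 72 h. The counts of differences between times were sensitive to single arrays. The 72 h against 24 h count of 176 was 94, 85 and 48 without control 24 h replicate 1, 2 and 3, and 49, 48 and 115 without the depleted ones. It was 44, 99 and 60 without control 72 h replicate 1, 2 and 3, 69, 74 and 41 without the depleted ones, 106 without control 48 h replicate 1 and 112 without depleted 48 h replicate 3. The F-test count of 85 was 48 and 43 without control 24 h replicate 1 and 3, and 40 and 52 without depleted 24 h replicate 1 and 2. It was 49 and 54 without control and depleted 48 h replicate 1, 24, 30 and 30 without control 72 h replicate 1, 2 and 3, and 20, 24 and 25 without the depleted ones.

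Control cells were compared between 72 h and 24 h as the background of time in culture. In these cells DDIT4 rose by 2.16 (SE 0.30, adjusted p = 0.00632, limma, n = 3 per group), ALDH1L2 by 1.85 (SE 0.20), KLHL24 by 1.71 (SE 0.25), STC2 by 1.67 (SE 0.23) and the transcription factor CEBPB by 1.57 (SE 0.24). CCL20 (-2.70, SE 0.47), NPPB (-2.64, SE 0.36), the chemokine CXCL10 (-1.89, SE 0.27) and TXNIP, the thioredoxin inhibitor (-1.76, SE 0.24), were lower. The cyclophilin PPIL2 was called lower by 1 probe set while its most abundant one was at -0.11 and did not pass (adjusted p = 0.999). CCL20, CEBPB and KLHL24 lost their call in 5, 3 and 1 of the 18 fits that left out 1 array. ATF4 targets were called higher (7 of 33, 23 adjusted over the list alone, median 0.88, adjusted p = 6.93e-35, and 0.000156 with an estimated correlation). The NF-kB list was called lower (5 of 16, 8 adjusted over the list alone, median -0.81, adjusted p = 8.3e-18, and 1.64e-05). Ribosome biogenesis (2.23e-07) and heat shock proteins (5.02e-06) were called lower and cholesterol synthesis higher (0.00746), also with an estimated correlation. Lower G1/S (0.00208), complexes II to V (0.00275) and fibroblast markers (0.0421) and higher hepatocyte markers (0.00208) and fatty acid synthesis (0.00385) lost their call, with adjusted p = 0.196, 0.236, 0.119, 0.227 and 0.236 with an estimated correlation. With the block the fibroblast call was lost (adjusted p = 0.0739) and complex I was called lower (0.0251), though not with the block and an estimated correlation (adjusted p = 0.473). Cholesterol synthesis lost its call with the block and an estimated correlation (adjusted p = 0.0621).

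Limma called 32 probe sets in control cells, 14 higher and 18 lower at 72 h, and 332 with the replicate block, 199 higher and 133 lower. The count was 15, 14 and 14 without control 72 h replicate 1, 2 and 3 and 15 and 17 without control 24 h replicate 2 and 3. Without the suffixed arrays it was 13 (241 with the block). This comparison shares its 24 h control arrays with the depletion effect at 24 h. In both comparisons 10 probe sets were called, all in the same direction, against 0.0319 for independent calls. Across probe sets the log2 fold changes of both comparisons correlated at 0.480, and simulated arrays with no difference between groups gave 0.500 from the shared arrays alone. With 3 control arrays the controls could not be split into separate groups of at least 2 arrays.

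In depleted cells between 24 and 72 h the metallothionein probe sets of MT1H (2.63, SE 0.39) and MT1X (1.95, SE 0.40) rose, with NPPB (2.13, SE 0.36), PTGS2 (1.89, SE 0.33), EMP1 (1.80, SE 0.35) and RGCC (1.76, SE 0.28). Over the same time TXNIP (-2.20, SE 0.24), LAMA1 (-1.73, SE 0.36), GAS2 (-1.58, SE 0.35) and CHI3L1 (-1.34, SE 0.30) fell. Limma called 565 probe sets, 257 higher and 308 lower, and 2812 with the replicate block, 1194 higher and 1618 lower. Centred on the 75th percentile 203 were higher and 161 lower, and with no filter on low values 169 and 161, so which direction held more probe sets depended on the setting. Metallothioneins (4 of 9 higher, 6 adjusted over the list alone, adjusted p = 1.54e-06, and 0.0216 with an estimated correlation) and NRF2 targets (2 higher and 1 lower of 27, 5 higher and 1 lower adjusted over the list alone, 0.00426, and 0.034) were called higher. Another 8 calls were lost with an estimated correlation. These were lower fatty acid oxidation (adjusted p = 0.000208, and adjusted p = 0.219 with an estimated correlation), G1/S (0.0087, and 0.232) and complex I (0.0112, and 0.569). The others were higher ATF4 targets (0.00426, and 0.23), ribosome biogenesis (0.0043, and 0.21), SMAD (0.0087, and 0.173), hypoxia (0.0112, and 0.0585) and NF-kB (0.0304, and 0.127). With the block G2/M was also called lower (adjusted p = 0.0267, against 0.108 without it), but not with the block and an estimated correlation (adjusted p = 0.507). Metallothioneins and NRF2 targets lost their call with the block and an estimated correlation (adjusted p = 0.0549 and 0.131). The count was 123 and 192 without depleted 24 h replicate 1 and 2 and 212, 177 and 176 without depleted 72 h replicate 1, 2 and 3. Without the suffixed arrays it was 258 (2351 with the block).

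**Figure D3:**
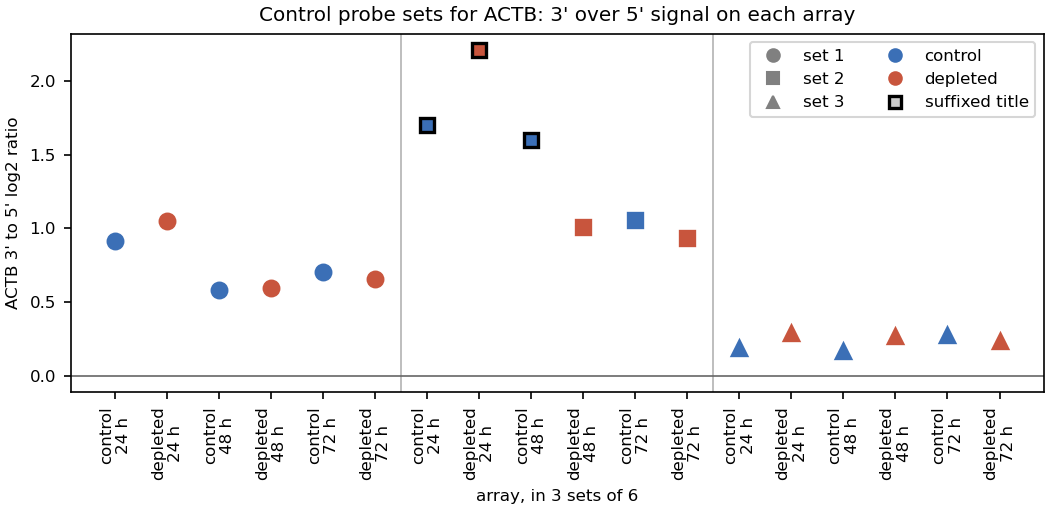
Log2 ratio of 3' to 5' signal of the ACTB control probe sets (y axis) on each of the 18 arrays, by set of 6 arrays (x axis) and medium. The 3 suffixed arrays of set 2 lay between 1.6 and 2.21, the other 3 of that set between 0.93 and 1.06, set 1 between 0.58 and 1.05 and set 3 between 0.17 and 0.29.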

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

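Of the tests in this part, those of the control cells at 24 h and of the scaling for the ATF4 genes (the latter in place of one whose settings moved too little to decide), and the replicate block as the spread of the simulated shared controls, were chosen after seeing the result. The genes and lists named first stood out because the direct test found their depletion effect to differ between times. Between 24 and 72 h the effect rose by 4.78 on the log2 scale for NPPB, 4.48 for CCL20, 2.94 for PTGS2, 2.84 for the MT1H probe set, 2.64 for RGCC, 2.58 for MMP1, 2.05 for GPRC5A, 1.80 for GPX2 and 1.73 for THBS1, the calls of GPRC5A and THBS1 each being lost in 7 of the 18 fits that left out 1 array. It changed by -2.54 for STC2, -2.54 for ALDH1L2, -2.52 for GAS2 and -2.09 for RPGRIP1L. Among these genes only NPPB, ALDH1L2, GPRC5A and THBS1 were followed through those fits for this difference. For SETBP1, which stood out by the F-test over all times, the change from 24 to 72 h was -0.41. The list medians changed by 1.25 for NF-kB, 1.09 for metallothioneins, 0.56 for ribosome biogenesis, 0.35 for heat shock proteins, 0.34 for SMAD and 0.29 for NRF2 targets, and by -0.62 for ATF4 targets, -0.48 for fatty acid oxidation and -0.26 for cholesterol synthesis. With an estimated correlation heat shock proteins (adjusted p = 0.0856), SMAD (0.141), fatty acid oxidation (0.233) and cholesterol synthesis (0.0856) lost their call, and with the block as well those of ATF4 targets (0.128), NRF2 targets (0.128) and metallothioneins (0.0677) were lost too.

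The NF-kB and ATF4 genes also moved over time in control cells. The mean level of the NF-kB genes, centred over all arrays, was 0.39, -0.02 and -0.61 in control cells at 24, 48 and 72 h and -0.16, 0.18 and 0.21 in depleted cells. That of the ATF4 genes was -0.58, -0.31 and 0.31 in control and 0.20, -0.09 and 0.47 in depleted cells. Metallothioneins reached 1.09 only in depleted cells at 72 h, and in control cells their change over time was not called (adjusted p = 0.88). Between 24 and 72 h heat shock proteins went from 0.20 to -0.19 in control and from -0.11 to -0.19 in depleted cells. Cholesterol synthesis went from 0.10 to 0.35 and from -0.24 to -0.31. In depleted cells neither change was called (adjusted p = 0.748 and 0.67, camera), so both shifts lay mostly in control cells. Ribosome biogenesis went from 0.10 to -0.21 in control and from -0.23 to 0.02 in depleted cells.

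The count of probe sets whose effect differed between times was 85 by the F-test (953 with the replicate block) and 176 for 72 h against 24 h (1251 with the block). When the labels of control and depleted arrays were exchanged within each time in 100 splits, the real one included, 2 splits gave an F-test count as large (85 against 103 at most in another) and 1 did for 72 h against 24 h (176 against 80). The split with 103 kept 2, 2 and 0 truly depleted arrays at 24, 48 and 72 h, so it exchanged all labels at 72 h and turned part of the depletion effect itself into a difference between times. For the averaged effect 1 split was as large (1162 against 26), and for the lists 2 were (13 against 13), the other keeping 2, 2 and 3 truly depleted arrays. Lists were also called in splits with 0 probe sets called in the average. A split that kept 1, 1 and 1 truly depleted arrays, and so part of the depletion effect with its sign reversed, called 10 lists. It parted only 3 of the 9 pairs of the same set and time, so differences between sets entered it too. Which of these gave its list calls cannot be told. In the 50 splits that parted every pair, the highest other count was 306 without and 2181 with the block, against 1162 and 4097.

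Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. In each the real split alone, 1 of 10, reached its count, with 59 at 24 h, 22 at 48 h, 1136 at 72 h and 32 in control cells over time against 0 at most in another split, and 565 in depleted cells over time against 1.

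The ATF4 and amino acid response genes were 0.783 higher (log2, list mean) in depleted than in control cells at 24 h. A difference due to RNA quality of the suffixed arrays would have shrunk without them, but 0.744 remained. In sets 1 and 3 the ACTB ratio was also higher in the depleted array at 24 h, by 0.13 and 0.10, and this test does not cover RNA quality there. A difference in scaling would move all probe sets of like signal. Their median difference at 24 h was at most 0.0557 in the 12 signal bins that hold these genes, against a list median of 0.714. Control cells at 24 h lay -0.698 from the mean of the other 5 groups, and depleted cells at 24 h lay 0.200 above the mean of control cells at 48 and 72 h (SE 0.0936, with the block 0.0862). They lay 0.511 above control cells at 48 h but -0.110 from those at 72 h (SE 0.108). A response to the depleted medium and control cells at 24 h that stand apart therefore cannot be told apart for these genes, because no further group without depletion was sampled at 24 h. Whether the media differed in more than riboflavin is also unknown. The covariance of the 24 h effect with the change of control cells over time, which share the control arrays at 24 h, was 0.0651 against 0.0388 simulated from the shared controls with the blocked spread (difference 0.0263) and 0.0676 with the unblocked spread (difference -0.00250), so part of the 10 probe sets called in both may come from the shared controls.

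Fewest probe sets were called at 48 h, 22 against 59 at 24 h and 1136 at 72 h (189, 646 and 3631 with the block), but array weights gave 410 at 48 h against 68 at 24 h, and without the suffixed arrays and without set 2 the counts were 7 against 3 and 2 against 1, while without the suffixed arrays under the block they were 109 against 309, so the order of 48 h and 24 h depends on the setting. Each of 3 explanations could hold: the 48 h difference of set 2, where only the control array had the suffix, correlated at -0.334 over probe sets with the signature of the suffix, as RNA quality would give. The spread between sets at 48 h was 1.2 times that of the larger of the other times (0.353 against 0.294 and 0.275), barely at the bound fixed for it. The depletion effect beyond noise was also smaller at 48 h, with an SD of 0.230 against 0.252 at 24 h and 0.406 at 72 h. The differences of sets 1 and 3 correlated at 0.306 at 48 h, against 0.336 at 24 h and 0.558 at 72 h. Those of set 2 correlated with sets 1 and 3 at 0.121 and 0.0566 at 48 h, against 0.249 and 0.280 at 24 h and 0.474 and 0.456 at 72 h. The lower correlation at 48 h than at 24 h thus lay mostly in set 2. Leaving out set 1, 2 or 3 at 48 h gave 1, 9 or 2 calls (35, 26 and 19 with the block), which also leaves fewer arrays, and these tests do not rank the explanations.

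Probe sets without a gene name made up 92 of 745 higher but 28 of 417 lower calls of the averaged effect (12.3 and 6.71 percent, against 12.0 percent of those tested), an odds ratio of 1.96 (95 percent interval 1.24 to 3.16, Fisher's exact test, p = 0.00246) and 2.19 with the replicate block. RNA quality of the suffixed arrays is unlikely, since the ratio was 2.45 (1.40 to 4.52) without them. Within 5 strata of mean signal it was 1.44 (0.907 to 2.30), so low signal of unnamed probe sets may account for it. After quantile normalization it was 1.48 (0.944 to 2.35), so a shift in scaling may as well. No biological explanation was tested.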

How the results depend on the processing

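The settings without the suffixed arrays, without set 2 and with the ACTB ratio as a covariate were chosen after seeing the data, and the others before. No gene or list called in the main fit or in an alternative changed its sign between them. Changes of sign among results called in neither were not counted. Which direction held more probe sets did change for some counts, as at 72 h, with 609 higher and 527 lower but 1748 and 1883 with the block. Of the comparisons of a setting with a result, genes kept their status in 5514, gained a call in 175 and lost it in 593. Lists kept it in 3853, gained a call in 35 and lost it in 108. Kept status includes results called in neither fit. Counts stayed within 1.5 times in 159 and moved further in 138. Apart from the causes given here, the cause was not tested.

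With the replicate block the counts rose to 646 at 24 h, 189 at 48 h, 3631 at 72 h, 4097 in the average, 953 by the F-test, 1251 for 72 h against 24 h, 332 in control cells over time and 2812 in depleted cells over time, because the spread between sets leaves the error. With the set as a random block they were 523, 181, 3253, 3618, 864, 1074, 260 and 2437 in the same order. With the ACTB ratio as a covariate beside the block they were 694, 207, 4216, 4755, 1071, 1250, 301 and 1035, and without the suffixed arrays under the block 309, 109, 5011, 4131, 915, 1208, 241 and 2351. The block kept all 1162 calls of the average and all 1136 at 72 h, and beyond the list calls named in the comparisons, at the preset or an estimated correlation, it changed no other call of a list.

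Fewer arrays mostly lowered counts. Without the 3 suffixed arrays they were 3 at 24 h, 7 at 48 h, 36 by the F-test, 47 for 72 h against 24 h, 13 in control and 258 in depleted cells over time. Without set 2 they were 1 at 24 h, 2 at 48 h, 717 at 72 h, 5 by the F-test, 10 for 72 h against 24 h, 6 in control and 109 in depleted cells over time. Leaving out 1 array at a time gave 20 to 61 at 24 h, 3 to 20 at 48 h, 576 to 1210 at 72 h, 794 to 1122 in the average, 20 to 90 by the F-test, 41 to 183 for 72 h against 24 h, 14 to 40 in control cells, 123 to 592 in depleted cells, and 12 to 14 lists. Separate fits of the groups compared, with fewer arrays for the variance, gave 0 with limma at 24 h, 48 h and in control cells over time (1637, 1545 and 1352 at an unadjusted p of 0.05), 410 at 72 h, 39 for 72 h against 24 h and 40 in depleted cells over time.

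Array weights gave 68 at 24 h, 410 at 48 h, 2595 at 72 h, 2475 in the average, 520 by the F-test, 426 for 72 h against 24 h, 75 in control and 1416 in depleted cells over time. Centring on the 75th percentile gave 25 at 24 h, 7 at 48 h, 49 by the F-test, 94 for 72 h against 24 h and 364 in depleted cells over time. Without a filter, which tests more probe sets, the counts were 39, 8, 41 and 65 for 24 h, 48 h, the F-test and 72 h against 24 h, and 330 in depleted cells over time. With the top 30 percent of probe sets they were 183 by the F-test, 269 for 72 h against 24 h and 53 in control cells over time. A pseudocount of 1 gave 14 at 48 h and 56 by the F-test, and 64 gave 93 at 24 h, 198 by the F-test, 268 for 72 h against 24 h and 60 in control cells over time. Quantile normalization gave 50 and a trended robust variance 56 in control cells over time. Of the 13 lists called in the average 8 were called with an estimated correlation.

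Signal over background limits weak genes, since the pseudocount of 16 lies close to the filter at a signal of 19.62. The median log2 difference over all probe sets was at most 0.0663 in size as reported, and at most 0.0792 in any setting other than leaving out 1 array.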

Other observations

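No test in this part was chosen after its result was seen, and no explanation is weighed. Of 22 measured p53 target genes 4 rose in the averaged effect and none fell, 5 adjusted over the list alone, while the list was not called (adjusted p = 0.147, camera in limma). These were GDF15, a stress-induced cytokine (1.26, SE 0.21), GADD45A, a growth arrest protein (0.95, SE 0.15), the kinase PLK2 (0.90, SE 0.15) and the death receptor TNFRSF10B (0.53, SE 0.13), whose call was lost in 11 of the 18 fits that left out 1 array. At 72 h they stood at 2.06, 1.91, 1.90 and 0.99. Of 23 enterocyte genes 3 rose and 5 fell, 3 and 6 adjusted over the list alone. The lower ones were FABP1, which binds fatty acids (-1.36, SE 0.34), carbonic anhydrase CA2 (-0.94, SE 0.15), the lipoprotein APOB (-0.94, SE 0.23), sucrase-isomaltase SI (-0.92, SE 0.14) and the epoxide hydrolase EPHX2 (-0.92, SE 0.20), and the higher ones the transcription factors KLF4 (0.88, SE 0.12) and KLF5 (0.74, SE 0.20) and the cytochrome CYP3A5 (0.84, SE 0.13).

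Of 30 hypoxia and glycolysis genes 4 rose and 2 fell, 5 and 6 adjusted over the list alone. The glucose transporter SLC2A1 (0.67, SE 0.17), the growth factor VEGFA (0.71, SE 0.18), the MYC antagonist MXI1 (0.84, SE 0.11) and the histone demethylase KDM3A (0.59, SE 0.14) were higher and the glycolytic enzymes LDHA (-0.56, SE 0.12) and PGAM1 (-0.55, SE 0.13) lower. Calls of KDM3A and PGAM1 were lost in 9 and 1 of the 18 fits that left out 1 array. Those of SLC2A1 and VEGFA were not followed through these fits. At 72 h the SMAD list held higher CCN1 and CCN2, matricellular proteins (2.13, SE 0.28, and 1.51, SE 0.38), and lower SMAD6, an inhibitor of BMP signalling (-1.51, SE 0.29), and the transcription factor MYC stood at 1.78 (SE 0.43). The iron exporter SLC40A1 rose in the average (0.55, SE 0.15) and ACO1, a cytosolic aconitase that senses iron, fell (-0.41, SE 0.11), each losing its call in 15 of these 18 fits.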
